A study of Drosophila melanogaster and Mus musculus with 8 samples.

How the data were processed

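Genomic DNA from adult fruit fly hindguts and ovaries and from mouse fetal livers at embryonic day 13.5 was sequenced with nanopore long reads, and transposon insertions absent from the reference genome were called by the authors. There were 8 libraries, 5 from flies and 3 from mice, with 1 library per group. Groups were taken from the tissue, genotype and treatment labels. The mouse control library was grouped by its genotype label, heterozygote, while its title calls it WT. The merged fly library was treated as a group of its own and never as a replicate, because it contains most calls of the single sh-dcramp1 hindgut library.

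Per the submitters' processing notes, minimap2 2.17-r941 and the genome builds dm6 (fly) and mm10 (mouse) were used. The insertion caller and its filters are not given in the sources used here. Each deposited line is a 200 bp bin with the transposon name, the counts of supporting reads and the read names. The deposited counts are whole numbers of reads and were not normalized: a count of reads that hold the insertion inside them (spanning reads) and a count of reads that end within it. The meaning of these counts was taken from their form, since the deposited files do not explain them. No line held more than 2 supporting reads in all. Each of the fly calls had a spanning read, while the mouse libraries held 0, 0 and 1 such calls. The mouse mutant and heterozygote files give transposon names without insertion coordinates, so mouse sites were placed by bin. The name of the AZT file lacks a mark that the names of both other mouse files carry, and its meaning is not given in the sources used here. Coordinates within the element exist for the fly libraries and the AZT-treated mouse library. The total reads sequenced are unknown, so numbers of calls are described with exact Poisson 95% intervals and were not compared as rates. All intervals, and the limit of 3 calls that a count of 0 allows, cover counting error only.

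A call was counted once, under the name of its spanning entry in flies and the first name listed in mice. Names were assigned to classes (LTR, LINE, DNA, other) and mouse groups (L1MdTf, L1MdA, L1MdGf, other L1, IAP, ETn/MusD, MERVL, RLTR4, VL30, other LTR, other) by lists written before the files were seen, and the prefixes that match the file names to those lists were set after. Shares of calls have exact Clopper-Pearson 95% intervals. In each of 8 comparisons, every family with at least 5 calls in the libraries compared was tested with Fisher's exact test (two-sided) of its calls against all other calls, giving a conditional odds ratio with its exact interval. Values of p were adjusted by the Benjamini-Hochberg method within a comparison, separately for families, classes and mouse groups, with a threshold of 0.05. With 1 library per group, each such test compares libraries and not conditions, and sites are not replicates. Shares sum to 100, so a large rise of 1 family lowers the shares of the others. Where a library had 0 calls of a family, the fold was computed against 3 calls and is a lower bound for the share observed in the other library, without that share's own error. The difference between hindgut and ovary in the sh-dcramp1 against sh-white log odds ratio was tested with a Wald test after adding 0.5 to each cell, as planned, and with Zelen's exact test of equal odds ratios, added later, whose p values are printed. Both gave the same calls.

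Calls of 2 libraries were taken as the same site when of the same family and within 50 bp, which for mouse bins means the same or adjacent bins. The 3′ end of an element in the AZT-treated library was set by the largest coordinate seen for its name. An insert was taken as full length when its span within the element reached 90% of the longest span seen for that family. Fly positions were compared with gene bodies of 17807 genes of the fly Release 6 annotation, the assembly of dm6. That table gives no exons and no strand, so exon, intron and sense to the gene were not analysed here. The share of calls in gene bodies was compared by Fisher's exact test in 5 fly comparisons, adjusted together. Mouse genes were not analysed here. The strand marks of the 2 reads supporting 1 fly call differed in 53 of 83 calls of the 4 single fly libraries, so orientation was not analysed. Allele fractions were not analysed because the counts of reads without the insertion were not used here.

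Families were named by a rule set before the data were examined: the 10 with most calls, every family past the threshold, and a fixed list of families in grouped sentences. Host genes were named when they held at least 3 separate sites in 1 library or belonged to a fixed list. The rule to name the 5 sites with most supporting reads could not choose, since sites tied at 2 reads, and the single sites named were chosen after their values were seen. The list of elements named for the Y chromosome (MURVY, IAPEY and YREP names) was also chosen after the data were seen.

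The family test was tested on simulated calls before use, with 200 simulations per setting. At the sizes of the hindgut libraries, a 4-fold change in the odds of copia was recovered in 96.5% of simulations and a 2-fold change in 21.5%. For the mouse mutant against the heterozygote, a 2-fold change of L1MdTf_III was recovered in 100% of simulations. In 23% of the latter, at least 1 unchanged family was called as its share fell. With no change, 2.5% of simulations of that comparison and 3.5% of those of the hindgut held a false call. Alternatives planned in advance were main chromosomes only, calls found in 1 library only, calls within 50 bp counted once, calls with more than 1 family name left out, a minimum of 10 calls, the merged library in place of the single library, other distances for shared sites, and other read minimums. Alternatives chosen after seeing the data were autosomal sites without elements named for the Y, calls with 1 supporting read, calls sharing a read with another call left out, rover calls left out, the additional calls of the merged library, Zelen's exact test, and gene bodies extended by 1000 bp on both sides. With no difference between tissues, Zelen's exact test gave an unadjusted p under 0.05 in 3%, 1% and 5% of simulations for the DNA, LINE and LTR classes. Computations used Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6 and matplotlib 3.10.9.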

Results

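Transposon insertions absent from the reference were compared between flies expressing a short hairpin RNA against dcramp1 (sh-dcramp1) and flies expressing a control hairpin against the eye colour gene white (sh-white), in adult hindgut and ovary, and between fetal livers of Cramp1 mutant mice, Cramp1 heterozygous mice and mutant mice given AZT. AZT (zidovudine) is a nucleoside analogue that blocks reverse transcriptases. The series' stated aim was to capture transposon mobilization in fly hindguts, and the mouse livers carry mutations of the related gene. The hindgut libraries held 171 insertion calls with sh-dcramp1 (95% CI 146 to 199) and 106 with sh-white (86.8 to 128). The ovary libraries held 51 (38.0 to 67.1) and 44 (32.0 to 59.1). A merged sh-dcramp1 hindgut library held 360 calls (324 to 399). The mouse libraries held 3914 calls in the heterozygote (3792 to 4039), 5568 in the mutant (5423 to 5716) and 2593 in the AZT-treated mutant (2494 to 2695). Most calls rested on a single read, 78.4% in the sh-dcramp1 hindgut, 70.8% in the sh-white hindgut and 92.1% to 96.8% in the mouse libraries. The depth of sequencing was unknown, so the shares of calls within each library were compared. There was 1 library per group, so no difference below has a replicate check and each test compares libraries rather than conditions.

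In the hindgut, the comparison of sh-dcramp1 with sh-white asked which transposons had gained insertions when dcramp1 was silenced. The LTR retrotransposon rover accounted for 37 of 171 calls with sh-dcramp1, 21.6% (95% CI 15.7 to 28.6), and for 0 of 106 with sh-white, which allows a share of up to 2.83%. The share of rover was at least 7.65-fold higher with sh-dcramp1 when 3 calls are set in place of 0, and the lower 95% limit of the odds ratio was 7.28 (Fisher's exact test, adjusted p = 6.57e-08). Copia, an LTR retrotransposon of another superfamily, gave 33 calls (19.3%, 13.7 to 26.0) against 11 (10.4%, 5.30 to 17.8), with an odds ratio of 2.06 (0.958 to 4.75) that did not pass (Fisher's exact test, adjusted p = 0.435). The 37 rover calls are part of the sh-dcramp1 total and lower the share of copia there. With rover left out, 0 of 13 families passed and 1 had an unadjusted p under 0.05. Rover and copia together were the families with most calls in the sh-dcramp1 hindgut, and roo and mdg1 were those with most in the sh-white hindgut.

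Of 14 families tested in the hindgut, rover alone passed. The LTR retrotransposons roo (16 against 15 calls), mdg1 (15 against 12) and gypsy (6 against 7), the last also known as mdg4, had shares of 9.36% against 14.2%, 8.77% against 11.3% and 3.51% against 6.60%. Among non-LTR retrotransposons, Doc gave 11 against 6 calls, jockey 6 against 5, F-element 5 against 5 and I-element 2 against 4. Of the other LTR families fixed in advance, 297 and 412 each gave 3 against 2 calls, blood 1 against 3, Tirant 1 against 0 and ZAM 0 against 1. The DNA transposons hobo and pogo gave 1 call each in both libraries. No call in any fly library carried the names Idefix, HeT-A, TART, R1, R2 or P-element. By class, LTR elements made up 78.9% (72.1 to 84.8) of calls against 68.9% (59.1 to 77.5), which did not pass (Fisher's exact test, adjusted p = 0.193), as no class did, adjusted or unadjusted.

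**Figure D1:**
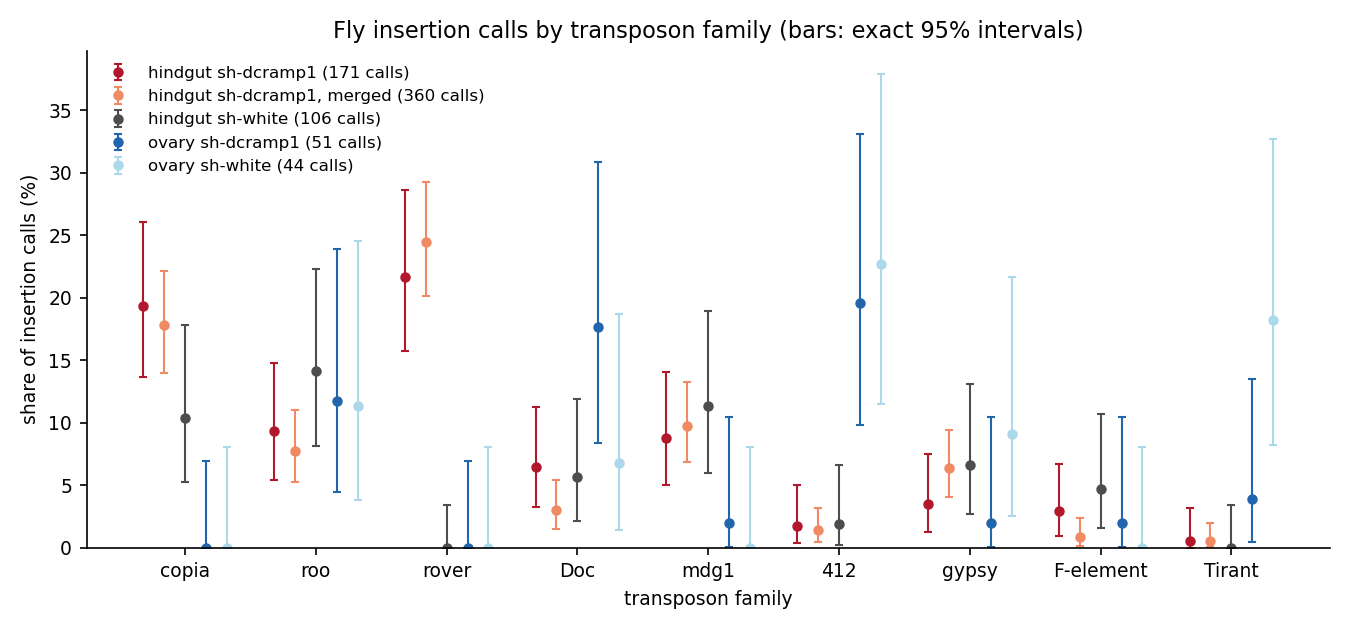
Share of insertion calls (%) of the 9 families with most calls in the single fly libraries, by library, with exact 95% intervals. Rover lies at 21.6% and 24.4% in the single and merged sh-dcramp1 hindgut libraries and at 0 in the sh-white hindgut and in both ovaries.

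The merged sh-dcramp1 hindgut library showed the same family at a similar level. Rover gave 88 of 360 calls, 24.4% (20.1 to 29.2), at least 8.64-fold above the sh-white hindgut (Fisher's exact test, adjusted p = 2.81e-10), and was the 1 family of 18 that passed. Copia gave 64 calls, 17.8% (14.0 to 22.1), against 10.4% (Fisher's exact test, adjusted p = 0.326). The next families were mdg1 with 35 calls (9.72%), roo with 28 (7.78%), gypsy with 23 (6.39%) and gtwin with 14 (3.89%). LTR elements were higher, at 86.9% of calls against 68.9% (odds ratio 3.0, 1.73 to 5.17, Fisher's exact test, adjusted p = 0.000161), and LINEs were lower, at 10.3% against 24.5% (0.353, 0.195 to 0.646, adjusted p = 0.000808).

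The merged library was not independent of the single library. It contained 150 of the 171 single-library calls, among them all 37 of rover, while the 21 calls it lacked included 3 each of Juan, Doc and F-element. A further 210 merged calls used no read of the single library, and 51 of these were rover, 24.3% (18.6 to 30.7). Against the sh-white hindgut, this share was at least 8.58-fold higher (Fisher's exact test, adjusted p = 2.62e-09). Between the additional and the single-library calls, rover differed by an odds ratio of 1.16 (0.699 to 1.94). LINEs made up 8.57% of the additional calls and 17.5% of the single-library calls, an odds ratio of 0.442 (0.222 to 0.856, Fisher's exact test, adjusted p = 0.0372), so the class shares also differed between calls of the same genotype and tissue. The merged library lacked 3 of 11 Doc, 3 of 5 F-element, 3 of 3 Juan, 1 of 6 jockey and 0 of 2 I-element calls of the single library. It lacked 0 of 37 rover, 1 of 33 copia, 0 of 16 roo and 0 of 15 mdg1 calls. An uneven loss of calls in the merged library therefore cannot be told apart from a difference in LINE share, there or among its additional calls.

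All 37 rover inserts of the sh-dcramp1 hindgut were full length, reaching at least 90% of the longest rover span seen, with a median span of 7305 bp (range 7246 to 7305). Copia inserts had a median span of 5113 bp, and 33 of 33 were full length. Across LTR families, 135 of 135 inserts in the sh-dcramp1 hindgut and 73 of 73 in the sh-white hindgut were full length. LINE inserts were full length in 20 of 30 (66.7%, 47.2 to 82.7) and 17 of 26 (65.4%, 44.3 to 82.8), and they reached the 3′ end of the element in 30 of 30 and 25 of 26.

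Rover sites lay on all large chromosome arms. Of the 37 sites in the single library, 30 lay inside gene bodies (81.1%, 64.8 to 92.0), where gene bodies cover 68.6% of the length up to the last gene of each chromosome (exact binomial test, adjusted p = 0.255). Among the rover sites with 2 supporting reads were the bins at 3L 1730601 to 1730800 in drpr, which encodes the engulfment receptor Draper, at 3L 4751201 to 4751400 in RhoGEF64C, at X 14584801 to 14585000 in sbm and at 2L 6614001 to 6614200 in CG11050. Those at 2R 8634201 to 8634400 and X 19960201 to 19960400 also had 2 reads and lay outside gene bodies. Copia also had a call in RhoGEF64C, at 3L 4716001 to 4716200. Copia sites lay in gene bodies in 25 of 33 cases in the single library (75.8%, 57.7 to 88.9, exact binomial test, adjusted p = 0.551) and in 55 of 64 in the merged library (85.9%, 75.0 to 93.4, adjusted p = 0.0116). All calls together gave 119 of 171 (69.6%, exact binomial test, adjusted p = 0.805) and 273 of 360 (75.8%, adjusted p = 0.0124). Host genes with 3 separate sites in 1 library were Hnf4, a nuclear receptor gene (2L 8687226 to 8709611; Burdock, gtwin and rover), and Trim9, a ubiquitin ligase gene (2L 10544883 to 10628054; 2 mdg1 and 1 rover), both in the merged library. Of 8 genes fixed in advance as known insertion targets, Bx (X 18515428 to 18572809) held 1 rover site in the merged library, and 0 of 11 members found in the annotation, from a fixed list of 14 gut and Polycomb genes, held a site. Su(z)2, a Polycomb-group gene outside that list, held 1 rover site in the single library (2R 13007725), also found in the merged library, and 1 copia site in the merged library (2R 13004451).

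**Figure D2:**
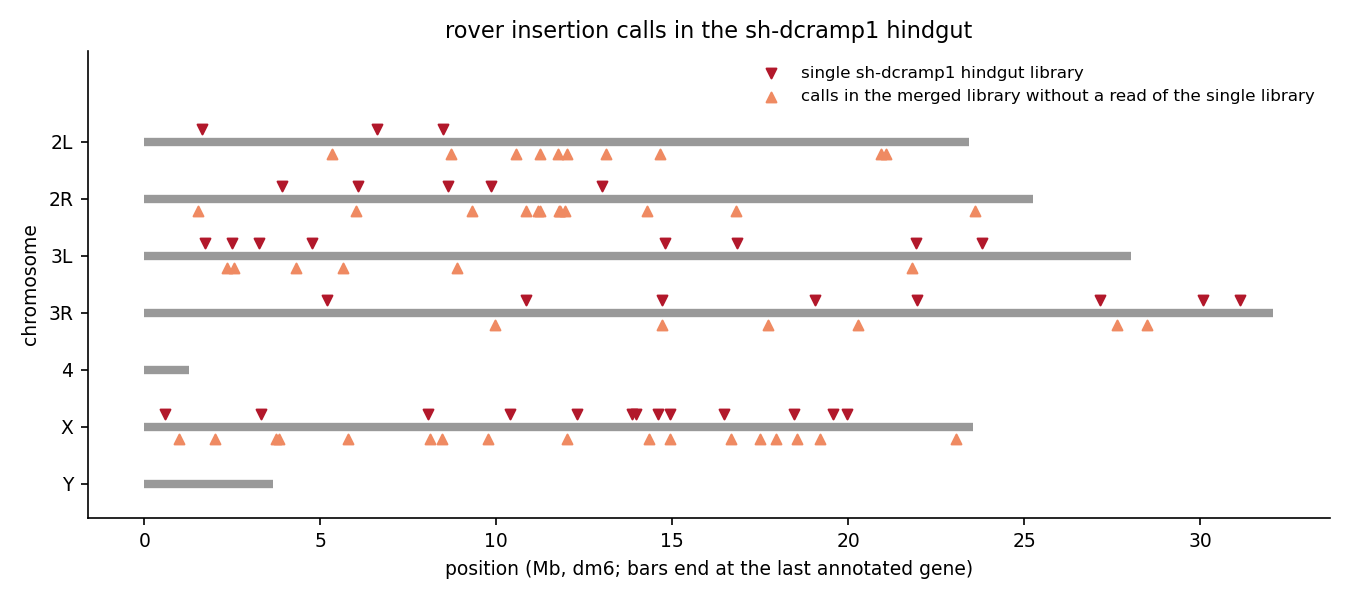
Positions of rover insertion calls in Mb on the dm6 chromosomes in the sh-dcramp1 hindgut. Downward triangles mark the 37 calls of the single library and upward triangles the 51 calls of the merged library with no read of the single library, with calls on 2L, 2R, 3L, 3R and X in both.

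In the ovary, the same comparison gave neither rover nor copia. Both families had 0 of 51 calls with sh-dcramp1, which allows up to 5.88%, and 0 of 44 with sh-white, which allows up to 6.82%. The LTR retrotransposon 412 was the most frequent family in both ovaries, with 10 of 51 calls (19.6%, 9.82 to 33.1) and 10 of 44 (22.7%, 11.5 to 37.8). Tirant, an LTR retrotransposon related to gypsy, gave 2 calls (3.92%) against 8 (18.2%), an odds ratio of 0.187 (0.0183 to 1.01, Fisher's exact test, adjusted p = 0.203). Roo gave 6 against 5 calls, Doc 9 against 3 and gypsy 1 against 4.

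None of the 5 ovary families tested passed, and Tirant was the 1 with an unadjusted p under 0.05 (Fisher's exact test, p = 0.0407). LINEs as a class were higher with sh-dcramp1, at 15 of 51 calls (29.4%, 17.5 to 43.8) against 3 of 44 (6.82%, 1.43 to 18.7), an odds ratio of 5.60 (1.42 to 32.6, Fisher's exact test, adjusted p = 0.0226). LTR elements gave 62.7% against 81.8% (Fisher's exact test, adjusted p = 0.0660), and passed when calls with 1 supporting read alone were used. Sites lay in gene bodies in 58.8% against 84.1% of calls, an odds ratio of 0.274 (0.0862 to 0.782) that did not pass after adjustment over the 5 fly comparisons of gene bodies (Fisher's exact test, adjusted p = 0.0557, unadjusted p = 0.0123). None of the 5 passed, and 3 had an unadjusted p under 0.05. The sh-white ovary library carries another date in its name than the 3 other single fly libraries, so batch and genotype cannot be told apart in the ovary.

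Between hindgut and ovary, the shares of 3 of 10 families differed with sh-dcramp1 and those of 2 of 11 with sh-white, while families such as roo, Doc, gypsy and 412 had calls in both tissues. With sh-dcramp1, rover was at least 3.68-fold higher (Fisher's exact test, adjusted p = 0.000157) and copia at least 3.28-fold higher (adjusted p = 0.000568) in hindgut than in ovary, and 412 was lower, at 1.75% against 19.6% (odds ratio 0.0744, 0.0126 to 0.306, adjusted p = 0.000157). None of 3 classes passed there, and 1 had an unadjusted p under 0.05. With sh-white, 412 was likewise lower in hindgut, at 1.89% against 22.7% (odds ratio 0.0668, 0.00680 to 0.335, Fisher's exact test, adjusted p = 0.000467), and Tirant was at least 6.42-fold lower, at 0 of 106 against 8 of 44 calls (adjusted p = 0.000371). Copia with sh-white gave 10.4% in hindgut against 0 in ovary and mdg1 11.3% against 0 (Fisher's exact test, adjusted p = 0.0936 and 0.0687). LINEs with sh-white were higher in hindgut, at 24.5% against 6.82% (odds ratio 4.41, 1.24 to 24.1, Fisher's exact test, adjusted p = 0.0369), a call lost with calls of 1 supporting read. Tissue and date cannot be told apart in the sh-white comparison.

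The difference between tissues in the effect of sh-dcramp1 was tested directly. For rover, the log odds ratio was higher in hindgut than in ovary by 4.23 (SE 2.47, natural log), which did not pass (Zelen's exact test of equal odds ratios, adjusted p = 1). This exact test cannot call a family with 0 ovary calls. Of 19 families, 0 passed it and 0 had an unadjusted p under 0.05, and the planned Wald test gave the same counts. The sh-white ovary library, with its other date, enters this test too. The LINE and LTR classes passed both tests, with LINEs lower and LTR elements higher with sh-dcramp1 in hindgut relative to ovary.

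In the mouse fetal liver, the mutant was compared with the heterozygote to ask whether Cramp1 loss changed which transposons gave insertions. L1 elements, the non-LTR retrotransposons of mammals, made up 62.7% (61.4 to 64.0) of mutant and 61.1% (59.5 to 62.6) of heterozygote calls (Fisher's exact test, adjusted p = 0.195). The young and active L1MdTf subfamilies gave 14.9% (13.9 to 15.8) and 14.7% (13.6 to 15.9), L1MdA 10.6% and 11.0%, and L1MdGf 10.5% and 10.8%. Of 11 groups and 3 classes, 0 passed the test, and 4 groups and 0 classes had an unadjusted p under 0.05. With calls of more than 1 name left out, 3 groups passed, IAP (odds ratio 0.843), RLTR4 (2.22) and other L1 (1.13), and with calls that share a read left out, 2 passed, IAP (0.830) and other L1 (1.16).

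Of 106 families, 4 passed in this comparison. The internal part of MERVL, an endogenous retrovirus active in the early embryo, gave 5.62% of mutant against 4.14% of heterozygote calls (odds ratio 1.38, 1.13 to 1.69, Fisher's exact test, adjusted p = 0.030), and L1MdF_III gave 2.42% against 1.43% (1.71, 1.24 to 2.39, adjusted p = 0.0218). MURVY-int, a retrovirus repeated on the Y chromosome, was lower at 1.28% against 2.66% (0.473, 0.344 to 0.648, Fisher's exact test, adjusted p = 0.000130), as was IAPEYI, an IAP element of the Y, at 1.28% against 2.22% (0.568, 0.408 to 0.789, adjusted p = 0.0218). Of the families with most calls, L1MdTf_III gave 11.4% against 10.9%, L1MdF_I 10.1% against 9.76%, L1MdGf_I 9.55% against 10.2%, L1MdF_II 4.24% against 4.68%, the MERVL LTR 3.41% against 3.68%, L1MdA_III 3.0% against 3.01%, IAPLTR1a_I 2.55% against 2.48% and IAPEZI 2.01% against 2.22%. Of the other groups, IAP gave 9.66% against 11.2%, MERVL 9.03% against 7.82%, RLTR4, related to murine leukaemia virus, 0.736% against 0.332%, ETn/MusD 1.74% against 1.94% and VL30 0.323% against 0.383%. No call carried a B1 or B2 name, which allows up to 0.0539% of mutant calls if the caller searched for these names. Whether it did is not known, so the 0 may have been fixed in advance.

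The libraries also differed in their calls on the sex chromosomes and of elements named for the Y. Sites on the Y were 5 of 5568 mutant calls (0.0898%) and 22 of 3914 heterozygote calls (0.562%), an odds ratio of 0.159 (0.0470 to 0.431). The AZT-treated mutant had 10 of 2593 (0.386%). Elements named for the Y, at sites off the Y, made up 4.62% of mutant and 7.50% of heterozygote calls (odds ratio 0.597, 0.500 to 0.713). Among calls of other elements, sites on the X made up 5.43% and 4.25% (odds ratio 1.29, 1.05 to 1.59). With autosomal sites alone and elements named for the Y left out, 0 of 92 families passed and 6 had an unadjusted p under 0.05. The odds ratios of MERVL and L1MdF_III were then 1.32 and 1.59 (Fisher's exact test, adjusted p = 0.183 for both).

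**Figure D3:**
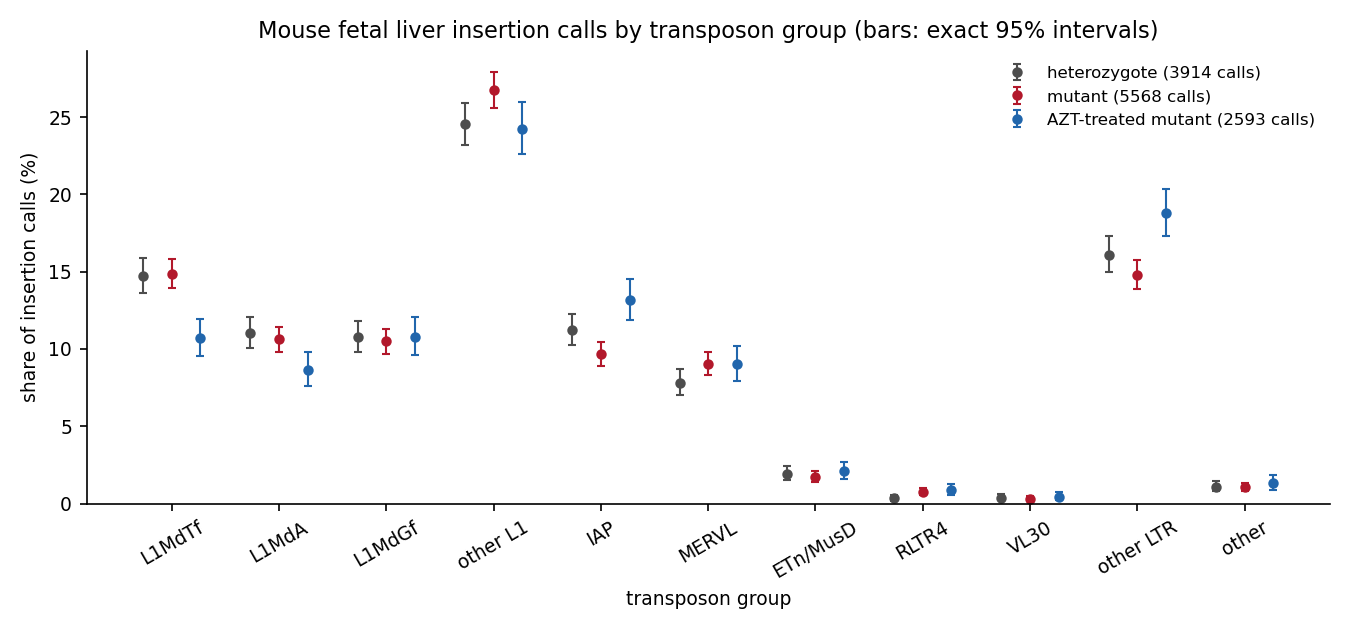
Share of insertion calls (%) by transposon group in the 3 mouse fetal liver libraries, with exact 95% intervals. L1MdTf lies at 14.7% and 14.9% in the heterozygote and mutant and at 10.7% in the AZT-treated mutant.

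The AZT-treated mutant was compared with the untreated mutant to ask which transposon shares differ when reverse transcriptase is blocked. The name of the AZT file lacks a mark that the names of both other mouse files carry, and its meaning is not given in the sources used here, so filtering and treatment cannot be told apart in the AZT comparisons. L1 elements were lower with AZT, at 54.4% (52.4 to 56.3) against 62.7% of calls (odds ratio 0.710, 0.645 to 0.781, Fisher's exact test, adjusted p = 3.94e-12), and LTR elements were higher, at 44.3% against 36.3% (adjusted p = 7.43e-12). L1MdTf was lower at 10.7% (9.52 to 11.9) against 14.9% (odds ratio 0.686, 0.591 to 0.794, Fisher's exact test, adjusted p = 2.34e-06), and L1MdA at 8.64% against 10.6% (0.796, 0.674 to 0.938, adjusted p = 0.0151). Other L1 was lower at 24.3% against 26.7% (0.878, 0.787 to 0.979, Fisher's exact test, adjusted p = 0.0402). L1MdGf, by contrast, gave 10.8% against 10.5% (1.03, 0.885 to 1.20). IAP elements were higher at 13.2% against 9.66% (1.42, 1.22 to 1.64, Fisher's exact test, adjusted p = 1.84e-05), as were other LTR elements at 18.8% against 14.8% (1.33, 1.18 to 1.51, adjusted p = 2.10e-05).

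Of 105 families, 4 passed between the AZT-treated and untreated mutant. L1MdA_II was lower at 0.386% against 1.67% (odds ratio 0.228, 0.106 to 0.439, Fisher's exact test, adjusted p = 8.81e-06), L1MdF_I at 7.37% against 10.1% (adjusted p = 0.00196) and L1MdTf_III at 8.72% against 11.4% (adjusted p = 0.00528), while IAPEYI was higher at 3.05% against 1.28% (2.43, 1.74 to 3.41, adjusted p = 8.81e-06). IAP elements not named for the Y gave 7.94% against 7.15% (1.12, 0.936 to 1.34). MERVL gave 9.02% against 9.03%, RLTR4 0.848% against 0.736%, ETn/MusD 2.08% against 1.74% and VL30 0.424% against 0.323%, none of which passed. With autosomal sites alone and elements named for the Y left out, L1MdTf remained lower (0.724) and other LTR elements higher (1.30), while L1MdA (0.847), other L1 (0.931) and IAP (1.21) no longer passed, IAP still with an unadjusted p under 0.05. L1MdA (0.827) and other L1 (0.879) also did not pass when calls of 1 supporting read alone were used, nor did other L1 (0.915) with calls found in 1 library only.

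Against the heterozygote, the AZT-treated mutant was again lower in L1MdTf and L1MdA, but other L1 did not pass, at 24.3% against 24.6% (odds ratio 0.984, 0.875 to 1.11). L1 elements as a whole gave 54.4% against 61.1% (odds ratio 0.759, 0.686 to 0.841, Fisher's exact test, adjusted p = 2.37e-07), L1MdTf 10.7% against 14.7% (0.693, 0.593 to 0.809, adjusted p = 2.42e-05) and L1MdA 8.64% against 11.0% (adjusted p = 0.00883), with L1MdGf at 10.8% in both. RLTR4 was higher at 0.848% against 0.332% (2.57, 1.23 to 5.56, Fisher's exact test, adjusted p = 0.0231), as were IAP (adjusted p = 0.0473) and other LTR elements (adjusted p = 0.0195). The 4 families that passed of 98 were all L1 names with lower shares, L1MdA_II (0.386% against 1.58%), L1MdF_I (7.37% against 9.76%), L1MdTf_II (0.926% against 1.89%) and L1_Mus1_3end (0.0771% against 0.511%). With autosomal sites alone and elements named for the Y left out, L1MdA_II alone still passed, while the odds ratios of the other 3 moved little, from 0.735 to 0.755 for L1MdF_I, from 0.485 to 0.514 for L1MdTf_II and from 0.150 to 0.150 for L1_Mus1_3end. L1_Mus1_3end also did not pass with calls found in 1 library only, with calls of 1 supporting read, with calls within 50 bp counted once, or without calls that share a read. L1MdTf_II was lost as well when calls within 50 bp were counted once, and L1MdF_I without calls that share a read. RLTR4 and IAP did not pass when calls of 1 supporting read alone were used. RLTR4 also did not pass without calls that share a read, and IAP without calls of more than 1 name. At those autosomal sites, 4 groups passed instead of 5 and the IAP call was lost (1.09). IAP elements not named for the Y gave 7.94% against 7.41% (1.08, 0.891 to 1.30).

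**Figure D4:**
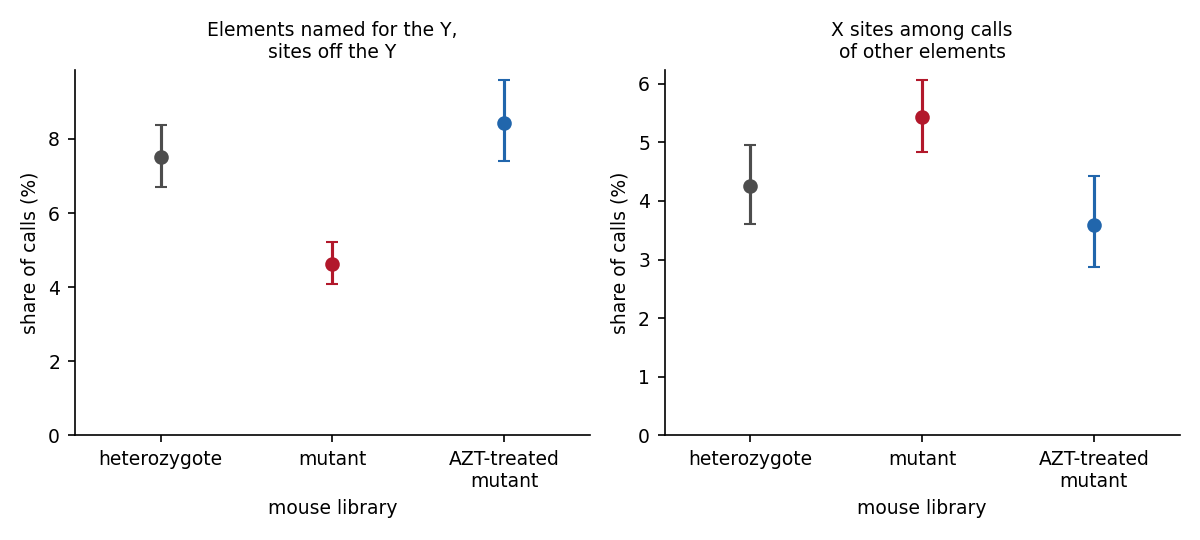
Share of calls (%) of elements named for the Y at sites off the Y (left) and of X sites among calls of other elements (right) in the 3 mouse libraries, with exact 95% intervals. The mutant is lowest on the left at 4.62% and highest on the right at 5.43%.

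Few sites recurred between libraries. In flies, apart from the merged library, at most 1 call was shared between any 2 libraries. In mice, 0 bins were identical between the mutant and the heterozygote, while the AZT-treated mutant shared 151 bins with the mutant and 107 with the heterozygote, whatever the family. The 21 calls of the mutant and the heterozygote within 50 bp of each other lay in adjacent bins. Whether the filters removed sites found in more than 1 library is not known. With at most 2 reads per call, sites carried in most cells may also have been left out. The low recurrence may therefore have been fixed in advance.

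In the AZT-treated library, where positions within the element are given, the share of junctions at the 3′ end of the element differed between L1 groups. The last 100 bp held 52.0% (45.9 to 58.0) of L1MdGf junctions, 37.9% (32.2 to 43.9) of L1MdTf and 30.4% (24.4 to 36.8) of L1MdA junctions, where an even spread would give 1.43%, 1.48% and 2.55%. Other L1, the group with most junctions (611), had 15.4% (12.6 to 18.5) there, with 1.81% under an even spread. The end is set by the largest coordinate seen for each name. For L1MdA_I this was 1712 bp, too short for a whole L1, and 1.89% of its junctions lay in the last and 71.7% in the first 100 bp. These 53 junctions are part of the L1MdA group and lower its value, so L1MdA cannot be ranked below L1MdTf here. The IAP group had 18.7% (14.4 to 23.6) in the last 100 bp, and IAPEZI 48.1% (36.7 to 59.6), with 1.58% and 1.57% under an even spread. The internal part of MERVL had 0.847% (0.0215 to 4.63), IAPEYI 2.53% (0.308 to 8.85), RLTR6I 2.70% (0.329 to 9.42) and MURVY-int 5.26% (1.10 to 14.6). For these, an even spread would give 1.83%, 1.34%, 1.30% and 1.38%, and each interval includes its value. The MERVL, IAPEYI, MURVY-int and IAPEZI names here are internal parts without LTRs, so their last 100 bp are not the end of the whole element. The MERVL LTR, named apart, had 63.8% (54.4 to 72.5) of 116 junctions in its first 100 bp. Its last 100 bp held 13.8% (8.09 to 21.4), where an even spread would give 20.4% for each. The internal part of MERVL, IAPEYI and MURVY-int were also among the families that passed between mutant and heterozygote, whose files give no such positions.

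**Figure D5:**
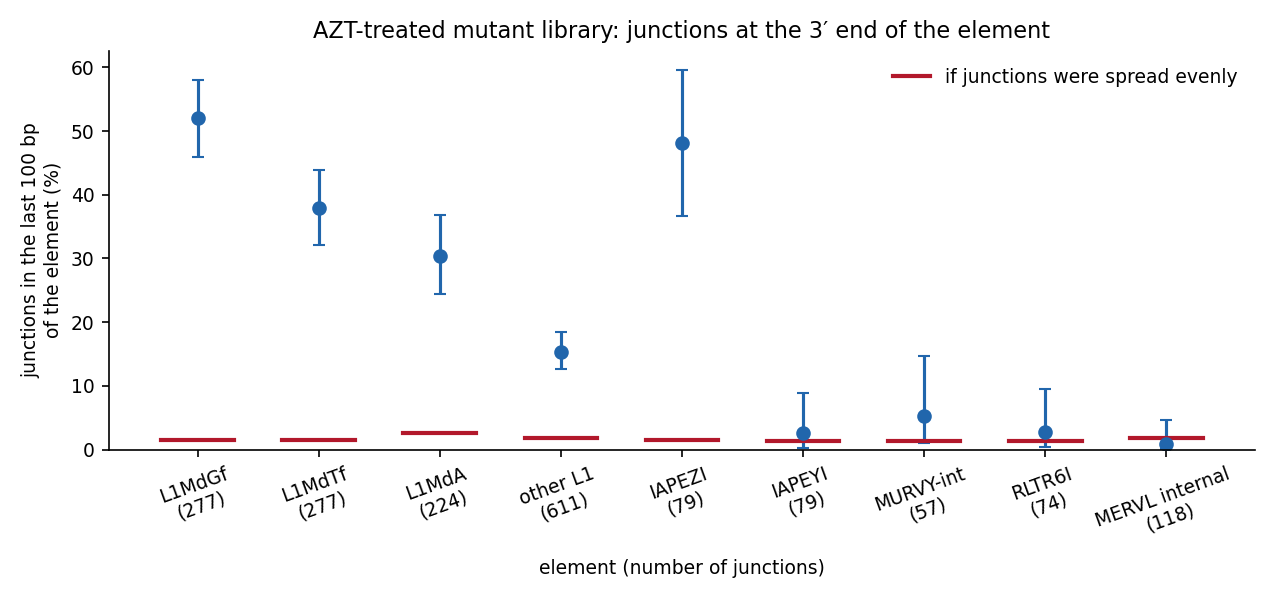
Share of insertion junctions (%) in the last 100 bp of the element in the AZT-treated mutant library, with exact 95% intervals and, as horizontal lines, the share under an even spread. L1MdGf, L1MdTf, L1MdA and IAPEZI lie between 30.4% and 52.0%, other L1 at 15.4% and the internal part of MERVL at 0.847%.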

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

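Zelen's exact test and the tests without rover and with the additional calls of the merged library were chosen after the results were seen. The effect of sh-dcramp1 on the share of LINE calls differed between fly hindgut and ovary, with a log odds ratio lower in hindgut by a difference of -2.04 (SE 0.701, natural log, Zelen's exact test of equal odds ratios, adjusted p = 0.00695). LINEs gave 17.5% with sh-dcramp1 against 24.5% with sh-white in hindgut and 29.4% against 6.82% in ovary. For LTR elements the difference was 1.47 (SE 0.553, Zelen's exact test, adjusted p = 0.0122), and both classes also passed the planned Wald test. Without rover, the LINE difference was -1.74 (Zelen's exact test, adjusted p = 0.0391) and the LTR difference 1.15 (adjusted p = 0.0859), which did not pass. The sh-white ovary library carries another date in its name than the other single fly libraries, so this difference cannot be told apart from one of batch. The ovary values rest on 51 and 44 calls, Doc supplied 9 of the 15 LINE calls in the sh-dcramp1 ovary, and the LINE share also differed between the single-library and the additional calls of the sh-dcramp1 hindgut.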

How the results depend on the processing

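Settings not planned in advance were autosomal sites without Y-named elements, calls of 1 supporting read, calls sharing a read left out, rover left out, additional merged calls, Zelen's exact test and extended gene bodies. Each result named in the design was paired with each alternative that applied to it. Of these pairs, 214 were the same, 26 moved and 1 was weaker. A count was called the same when it stayed within a set ratio of the main count, whichever families passed. With calls found in 1 library only, AZT against mutant families thus went from 4 to 6 and count as the same. The AZT against heterozygote families also count as the same there, at 4, though L1_Mus1_3end no longer passed. The causes were not tested except where the construction gives them. Rover passed in all 9 alternatives that kept it for the single hindgut library, and L1MdTf stayed lower with AZT in every alternative, against mutant and heterozygote alike. With Y-named elements and sex chromosome sites left out, families past the threshold went from 4 to 0 (mutant against heterozygote) and 4 to 1 (AZT against heterozygote), and groups from 5 to 2 (AZT against mutant) and 5 to 4 (AZT against heterozygote). Leaving out calls of more than 1 name moved groups from 0 to 3 (mutant against heterozygote), and leaving out calls that share a read moved them from 0 to 2 and the AZT against heterozygote families from 4 to 2. Counting calls within 50 bp once gave 2 of those families. A minimum of 10 calls, which tests fewer families, gave 7 instead of 4 for AZT against mutant. Calls found in 1 library only gave 4 instead of 5 groups for AZT against mutant. Calls of 1 supporting read gave 3 instead of 5 groups in both AZT comparisons, 2 instead of 1 class in the ovary and 0 instead of 1 between sh-white tissues. Leaving out rover removed the hindgut family call by construction (0 in the single and merged comparisons). In that setting, 1 of 13 families in the single and 2 of 17 in the merged comparison had an unadjusted p under 0.05. The merged library, and its additional calls, gave 2 classes in the hindgut instead of 0. Without rover, the LTR difference between tissues was 1.15 and no longer passed, while Zelen's exact test kept every class call. Within 10 bp, the 1 shared call of 4 fly pairs became 0, and with the wider distance planned the mutant and the heterozygote shared 49 calls instead of 21.

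Directions turned in odds ratios that passed no test, most of them near 1. With Y-named elements and sex chromosome sites left out, mutant over heterozygote gave LINE 0.981, LTR 1.02, L1MdTf 0.976 and other LTR 1.01, AZT over mutant gave MERVL 1.03, and AZT over heterozygote gave other L1 1.01. With calls found in 1 library only, L1MdGf gave 0.896 (AZT over mutant) and 0.872 (over heterozygote), and other L1 gave 1.02. With calls of 1 supporting read, RLTR4 gave 0.935 (AZT over mutant) and ovary DNA elements 1.66 (from 0.667). With calls sharing a read left out, RLTR4 gave 0.993 (AZT over mutant), and AZT over heterozygote gave L1MdGf 0.996, VL30 0.912 and other L1 1.015. No call had at least 3 supporting reads and all had at most 2, so these settings gave no value or changed nothing. Allele fractions were not run. Upstream extension of genes needs strand and was replaced by extension on both sides, which by construction raised the share of length in genes (68.6% to 76.1%) and with it the gene body shares (83.0% in the single, 85.0% in the merged, 84.8% in the additional sh-dcramp1 hindgut calls, 78.3% in the sh-white hindgut, 72.5% in the sh-dcramp1 and 90.9% in the sh-white ovary). No paired analysis was possible because each group holds 1 library.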

Other observations

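The tests below were chosen after the data were seen, except that among calls found in 1 library only. The test at autosomal sites was also chosen after the data were seen, though before its own value was. Rover calls lay on the X more often than those of other families of the same library. In the single sh-dcramp1 hindgut library, 13 of 37 rover calls (35.1%, 20.2 to 52.5) and 22 of 134 others (16.4%) were on the X, an odds ratio of 2.74 (1.11 to 6.66, Fisher's exact test, unadjusted p = 0.0200). Among the additional calls of the merged library the values were 17 of 51 (33.3%) and 24 of 159 (15.1%), an odds ratio of 2.80 (1.26 to 6.14, Fisher's exact test, unadjusted p = 0.00752). Copia sites among those additional calls lay in gene bodies in 30 of 32 cases (93.8%, 79.2 to 99.2, exact binomial test against 68.6%, adjusted p = 0.0116), against 25 of 33 (75.8%) in the single library. All additional calls together gave 165 of 210 (78.6%, exact binomial test, adjusted p = 0.0116).

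The rover calls of the sh-dcramp1 hindgut may come from mobilization in the gut when dcramp1 is silenced, the explanation the design names. Deeper sequencing would raise the other families as much as rover, but their calls were 134 against 106, a ratio with an upper 95% limit of 1.65, where the lower limit for rover was 9.54. How depth acts on files limited to 2 reads per call was not tested. Reads joined at random would start and end anywhere in the element. All 37 rover inserts, and all 51 of the additional merged calls, were full length (lower 95% limits 90.5% and 93.0%). The fly files hold only calls with a spanning read. They do hold partial inserts: among LINEs of the same library, 20 of 30 were full length. Those LINE inserts reached the 3′ end in 30 of 30 cases, however, and LTR inserts of all families in that library were full length in 135 of 135. The filters of the caller are unknown and may have favoured such inserts. These values therefore cannot decide on random joining as a cause of the rover calls. An insertion carried by all flies would draw reads from the other library pooled in the merged one or, past 2 reads, drop out. Of 37 calls, 0 dropped out and 2 drew such a read (upper 95% limit 18.2%). Few outside reads were not particular to rover, as 5 of all 360 merged calls held reads of both. The files list no call past 2 reads, so insertions carried by all flies may have been left out beforehand. The other library may also have been too shallow to cover most sites, and its depth is unknown. This count therefore cannot decide on insertions carried by all flies. A rover insertion history that differs between the sh-dcramp1 and sh-white stocks or between single flies stays open, with 1 library per group.

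Elements named for the Y made up a smaller share of calls in the mutant mouse library than in the 2 others. A smaller share of Y-bearing DNA in the mutant library is a candidate explanation: X sites of other elements were more frequent there, with an odds ratio of 1.29 over the heterozygote, and less frequent in the AZT-treated mutant than in the mutant (0.650, 0.501 to 0.835). Both contrasts share the mutant library. The Cramp1 mutation alone cannot be told apart from this: the AZT-treated mutant differed from the mutant by an odds ratio of 1.90 (1.57 to 2.30), but the AZT file keeps bins found in the other mouse files and those share 0 bins with each other, so a difference in filtering could give that value. An effect of AZT on these elements stays open, and the sex of the embryos is not given in the labels.

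The lower L1 share of the AZT-treated library may reflect fewer new L1 insertions under the drug, which was not tested beyond the 1 library. Fewer X chromosomes as the whole cause are argued against by an odds ratio of 0.763 (0.683 to 0.852) over the heterozygote at autosomal sites with elements named for the Y left out. Sites kept in the AZT file but removed from the others cannot be told apart from this. The odds ratio over the mutant was 0.669 (0.606 to 0.739) among calls found in 1 library only, but a site removed from both other files would still count there as found in 1 library. More reads joined at random in the AZT library cannot be told apart from this: 37.9% of its L1MdTf junctions lay at the 3′ end, and the mutant file gives no positions to set beside that value. Other differences between the libraries also stay open.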
